A study of Oryctolagus cuniculus with 49 samples.

How the data were processed

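RNA was measured by sequencing in eyes of New Zealand white rabbits, a common laboratory breed, in which the lens had been removed and replaced by an artificial intraocular lens, and in unoperated eyes. Per the labels, total RNA was extracted from the iris and ciliary body or from the cornea, and libraries were built for the DNBseq platform. The labels describe 49 samples. The analysis covers the 26 iris and ciliary body libraries, and the 23 cornea samples are not analysed here. Groups were taken from the age and treatment labels of each sample.

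The deposited table gives FPKM, fragments scaled to transcript length and to all mapped fragments of a library, per RefSeq transcript and library, as named in the file header. The submitters' processing notes name HISAT2 2.0.4, HISAT, Bowtie2 2.2.5 and RSEM 1.2.12, without saying which step each served. The genome build and annotation release are not given in the sources used here. The table holds 16725 transcripts with values of 2 decimals, and 1.133% of the values are 0. Each transcript exceeds 1 FPKM in all libraries of at least 1 of 4 groups (operated juveniles of both ages together, unoperated 5-week, operated 6-month and unoperated 6-month eyes), and the smallest such group minimum is 1.01 FPKM. The choice of transcripts therefore depends on the groups, and a transcript low in every group cannot be seen. A list member low in all unoperated eyes is measured only if it is higher in an operated group, so shares of list members that rose with surgery may be too high. The p-values of list tests for surgery rest on the same members and may be too low for that reason. Of the fixed lists 10 of 25 neutrophil, 27 of 57 cytokine, 8 of 23 coagulation and 5 of 26 T and NK cell genes are measured. No read counts were used here, so the depth of each library is unknown and no counting intervals are given. FPKM is relative to the other transcripts of a library, so a few very abundant transcripts can lower all others.

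FPKM were summed over the transcripts of each gene symbol, which gave 12948 genes, 2672 of them with more than 1 transcript. Of 1880 symbols that were locus numbers or had been turned into dates, 190 were renamed through the RefSeq gene table of assembly mOryCun1.1, which was used for names only. It matched 9750 transcript accessions. Transcripts of near-identical gene copies, such as serum amyloid A, histocompatibility and globin genes, may share reads, and their values are uncertain to that extent.

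Values were analysed as log2(FPKM + 0.5), and genes at 1 FPKM or more in at least 3 libraries were kept, which removed none. Fold changes are on this scale, which understates the change of low genes. With limma 3.58.1 in R 4.3.3, 1 mean per group was fitted over all 26 libraries, with a mean-variance trend and robust moderation, and p-values were adjusted by the Benjamini-Hochberg method. Genes with an adjusted p under 0.05 are said to have risen, fallen or changed. The design foresaw a count model, and limma was the form it set for FPKM. The 6 comparisons were operated against unoperated eyes at 6 months, operated juvenile eyes (the mean of the 5-week and 6.5-week operated groups) against unoperated 5-week eyes, 6 months against juvenile among unoperated and among operated eyes, the difference of the 2 surgery effects (an interaction), and operated 6.5-week against operated 5-week eyes. No unoperated 6.5-week libraries exist in the labels, so surgery and growth are not separated in that group.

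The groups, the comparisons, 34 gene lists, most of the alternatives and the rule for naming genes were fixed before the data were examined. The alternatives chosen later are named in the part on how the results depend on the processing. By the rule, the text names the 6 largest rises and 6 largest falls of each comparison among called genes with a gene symbol, a mean of at least 1 FPKM and no overlap between the sides' libraries. It further names up to 4 members with the smallest p of each list described, members of the coagulation, fibrinolysis and complement lists at any p, and all called members of a sign where these are 5 or fewer. The rule allows 1017 gene values over the 6 comparisons, and those named were picked among them after their values were known, without a further rule. Surgery effects of LOX and COL1A1 are given outside the rule, and some genes that the rule allows are not reported here. Lists with at least 5 measured members were tested with camera, which compares a list with all other genes, at a preset inter-gene correlation of 0.01, and again with an estimated correlation. The fry test, which asks whether a list's genes move 1 way on balance, was an alternative. The gene ontology terms printed in the table, with 10 to 200 genes each, were tested in the same way.

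The procedure was tested on simulated data in which 200 of 12948 genes were changed. At a 2-fold change, 93% of the changed genes were found for the 6-month surgery comparison, 84% for the juvenile, 87% for age among unoperated eyes, 93% for age among operated eyes and 70% for the interaction. At 1.5-fold the shares were 63%, 74%, 73%, 71% and 41% in the same order, and false calls made up 4.9%, 6.5%, 3.6%, 7.3% and 6.7% of all calls. In a simulation of 30 lists, 0 unchanged lists were called and the 1 that was raised was called. Genes were drawn independently of each other in these simulations, so they cannot show false list calls that come from correlated genes. The simulated changes were few and evenly up and down, with the same spread in all groups and no shift between libraries. In the data 5969 of 12948 genes changed with surgery at 6 months, so the found and false shares need not hold there. No 2 libraries were identical. The labels give each sample a number but do not state that these mark separate animals, so p-values measure the spread between these samples. Alternatives covered scaling between libraries, pseudocounts of 0.1 and 1, filters, the juvenile operated groups taken singly, leaving out each library in turn, and samples with doubtful composition. Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9 were used for tables and plots.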

Results

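Transcript levels were measured in the iris and ciliary body of rabbits after lens removal with insertion of an intraocular lens. The series asks how coagulation and inflammation genes respond in the front of the eye and how this changes with age. The 26 libraries comprised 7 unoperated and 3 operated eyes at 5 weeks, 3 operated eyes at 6.5 weeks, and 7 unoperated and 6 operated eyes at 6 months. The sum of FPKM over the listed transcripts ranged from 412936 to 504202 per library, and the read depth is unknown. At 6 months the sum followed treatment, with 431241 to 456586 in unoperated and 476369 to 504202 in operated libraries. In juveniles the ranges overlapped, at 412936 to 438564 in unoperated and 437259 to 490542 in operated libraries. The main fit applied no further scaling between libraries, so the direction of small changes may depend on this shift. The time between surgery and sampling is not given in the sources used here.

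Operated and unoperated libraries were separated on the first principal component, which held 37.2% of the variance. Juvenile and 6-month libraries were separated on the second, which held 13.5%.

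**Figure D1:**
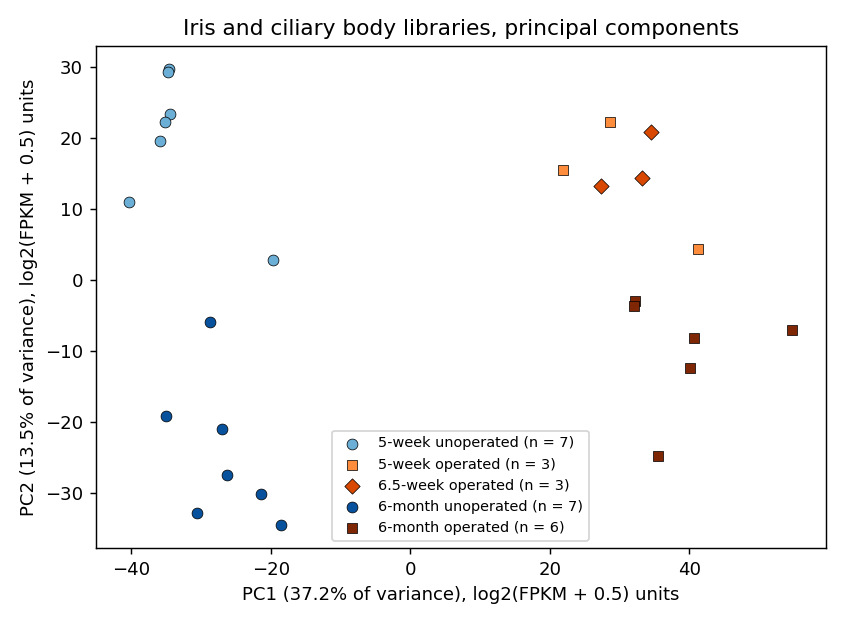
Each point is 1 iris and ciliary body library, placed by its first and second principal components of log2(FPKM + 0.5), which hold 37.2% and 13.5% of the variance. Operated libraries lie to the right of all unoperated ones, and juvenile libraries above all 6-month ones.

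At 6 months, surgery was followed by a large rise of acute phase and cytokine genes. SAA3, a serum amyloid A acute phase gene, averaged 20.9 ± 16.9 FPKM (SD, n = 7) in unoperated and 8490 ± 6080 FPKM (n = 6) in operated eyes, a log2 fold change of 8.75 ± 0.51 (SE; limma adjusted p = 6.27e-12). IL6, a cytokine that drives the acute phase response, stood at 0.0929 ± 0.162 FPKM in unoperated and 144 ± 43.7 FPKM in operated eyes (log2 7.92 ± 0.23). CHI3L1, LCN2, SERPINA3 and the chemokine CCL7 rose by log2 5.67, 5.20, 5.15 and 5.02. The anion exchanger SLC26A4 fell from 124 ± 24.3 to 4.18 ± 2.2 FPKM (log2 -4.83 ± 0.25). The carboxylesterase CES1, NPY, the retinoic acid hydroxylase CYP26C1 and the channel BEST2 had log2 fold changes of -3.97, -3.62, -3.24 and -2.90.

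Of 8 measured coagulation genes, 4 rose and 1 fell at 6 months by limma, or 4 and 2 adjusted over the list alone. VWF, the endothelial protein that tethers platelets, rose from 37.2 ± 4.97 to 111 ± 33.2 FPKM (2.86-fold). F3, the tissue factor gene that starts clotting, rose 1.86-fold from 4.15 ± 0.775 to 8.27 ± 1.9 FPKM. FGL1 rose from 0.171 ± 0.134 to 2.16 ± 0.799 FPKM, and FGL2, a prothrombinase, fell from 56.8 ± 6.0 to 21.6 ± 4.55 FPKM. TGM2 rose 1.33-fold, and its call was lost without unoperated replicate 5 or operated replicate 1, 2 or 3 (adjusted p up to 0.061), with libraries scaled to an equal sum (adjusted p = 0.112) and with lens and retina transcript levels as covariates (adjusted p = 0.089). Coagulation factor V (F5) did not pass (log2 -0.87 ± 0.38, adjusted p = 0.0611), but passed without unoperated replicate 2 or operated replicate 5 or 6 (adjusted p down to 0.0366) and in 4 other settings, among them equal-sum scaling and a fit on the compared groups alone (adjusted p = 0.0274 and 0.0284). The list as a whole did not stand apart from other genes (camera adjusted p = 0.135), and fibrinogen, prothrombin and plasminogen are not among the listed transcripts.

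Of 12 fibrinolysis and anticoagulant genes 9 rose and 1 fell at 6 months, or 10 and 2 adjusted over the list alone (camera adjusted p = 3.9e-05, adjusted p = 0.0143 with an estimated correlation). The protein C receptor PROCR rose 3.93-fold, the urokinase receptor PLAUR 3.8-fold and S100A10 1.78-fold. Thrombomodulin (THBD) and TFPI, both brakes on clotting, rose 1.58-fold and 1.48-fold, while protein S (PROS1) fell by 0.62 on the log2 scale (SE 0.08).

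**Figure D2:**
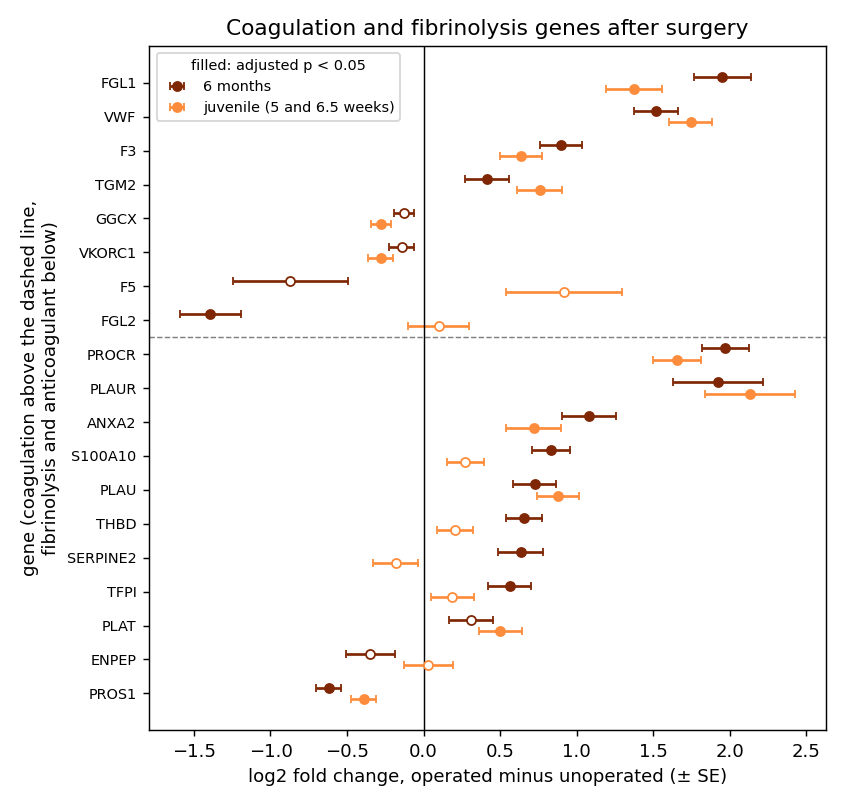
Log2 fold change of operated over unoperated eyes for coagulation genes (above the dashed line) and fibrinolysis or anticoagulant genes (below), without genes that are not reported here. Bars are standard errors, filled points have an adjusted p under 0.05, and PROCR lies to the right of 0 at both ages (log2 1.97 at 6 months and 1.66 in juveniles).

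Of 18 complement genes 12 rose at 6 months, and 12 also adjusted over the list alone (camera adjusted p = 4.3e-08, adjusted p = 0.0371 with an estimated correlation). Clusterin (CLU) went from 1020 ± 84.5 to 12500 ± 2900 FPKM, SERPING1 from 562 ± 85.9 to 1600 ± 326, CFB from 211 ± 47.5 to 603 ± 57.2 and CD55 from 27.7 ± 1.61 to 65.7 ± 16.1. C3, the central complement component, did not pass (log2 -0.01 ± 0.30, adjusted p = 0.983), and the sign of its value turned under median-ratio and upper-quartile scaling (log2 0.09 and 0.04).

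Of 27 acute phase and NF-kB genes 21 rose and 1 fell at 6 months, or 21 and 2 adjusted over the list alone (camera adjusted p = 4.84e-15, adjusted p = 0.0143 with an estimated correlation). SOCS3, which damps cytokine signalling, rose 12-fold and CEBPD 5.03-fold. Of 27 cytokines and chemokines 15 rose and 1 fell, with the same counts adjusted over the list alone (camera adjusted p = 1.04e-07, adjusted p = 0.0579 with an estimated correlation), and LIF rose 7.94-fold. Of 15 prostaglandin and leukotriene genes 8 rose and 2 fell, or 8 and 3 adjusted over the list alone (camera adjusted p = 0.00543, adjusted p = 0.0588 with an estimated correlation). The cyclooxygenases PTGS1 and PTGS2 rose 4.12-fold and 3.93-fold.

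Myeloid and cell cycle genes were also higher in operated 6-month eyes. Of 22 monocyte and macrophage genes 19 rose, or 20 adjusted over the list alone, with CD163 up 10.3-fold and CD209 21.4-fold (camera adjusted p = 4.77e-12, adjusted p = 0.0953 with an estimated correlation). Of 10 neutrophil genes 8 rose and 1 fell, or 9 and 1 adjusted over the list alone, with S100A8 up 22.9-fold and S100A9 8.75-fold (camera adjusted p = 8.35e-06, adjusted p = 0.0953 with an estimated correlation). Of 38 cell cycle genes 37 rose, and 37 adjusted over the list alone (camera adjusted p = 2.41e-33, adjusted p = 0.0213 with an estimated correlation), among them the cyclins CCNB2 (14.5-fold) and CCNB1 (13.7-fold), CDK1 (7.62-fold) and UBE2C (15.5-fold). Of 22 immediate early and stress genes 19 rose and 2 fell, the same counts adjusted over the list alone (camera adjusted p = 1.13e-12, adjusted p = 0.0633 with an estimated correlation). IER3 rose 10.4-fold and MYC 4.67-fold. Of 19 endothelial genes 12 rose and 1 fell, or 13 and 1 adjusted over the list alone, with CDH5 up 2.08-fold and SOX18 2.63-fold (camera adjusted p = 4.19e-07, adjusted p = 0.0956 with an estimated correlation).

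Genes of the resident epithelia and of smooth muscle fell at 6 months. Of 24 ciliary transport genes 16 fell and 3 rose, or 16 and 4 adjusted over the list alone (camera adjusted p = 0.000394, adjusted p = 0.189 with an estimated correlation), with BEST2 7.44-fold lower. Of 14 pigment cell genes 12 fell, or 13 adjusted over the list alone, with PMEL 3.54-fold and OCA2 1.96-fold lower (camera adjusted p = 0.000189, adjusted p = 0.0956 with an estimated correlation). Of 18 smooth muscle genes 13 fell, and 13 adjusted over the list alone, MYH11 2.5-fold and MYLK 2.02-fold (camera adjusted p = 0.00258, adjusted p = 0.265 with an estimated correlation). Of 13 junction genes of the blood-aqueous barrier 7 fell and 2 rose, the same counts adjusted over the list alone, with CLDN19 3.5-fold and CLDN3 2.4-fold lower and CLDN1 2.92-fold higher (camera adjusted p = 0.194).

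Extracellular matrix genes went both ways at 6 months. Of 40 such genes 19 rose and 11 fell, or 20 and 12 adjusted over the list alone (camera adjusted p = 0.000369, adjusted p = 0.189 with an estimated correlation). TIMP1, a metalloproteinase inhibitor, rose 4.02-fold, THBS1 8.38-fold and TGFBI 4.26-fold. Of 21 basement membrane genes 4 rose and 10 fell, or 5 and 11 adjusted over the list alone (camera adjusted p = 0.666), with COL4A2 3.22-fold higher and COL9A1 3.53-fold lower.

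In total 5969 of 12948 genes changed with surgery at 6 months, 2077 higher and 3892 lower, and 596 and 316 of them by 2-fold or more. The direction of small changes depended on scaling: 2784 rose and 2614 fell with median-ratio scaling, 2419 and 3237 with upper-quartile scaling, and 1441 and 6121 with libraries scaled to an equal sum, which moved the median log2 change of all genes from -0.105 to -0.245.

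Juvenile eyes were compared in the same way, with operated eyes of 5 and 6.5 weeks (n = 6) set against unoperated 5-week eyes (n = 7). SAA3 rose from 17.1 ± 19.4 to 7810 ± 2060 FPKM (SD), a log2 fold change of 9.23 ± 0.51 (SE; limma adjusted p = 3.27e-12). IL6, CHI3L1, SERPINA3, SOCS3 and LCN2 rose by log2 7.45, 6.42, 4.99, 4.51 and 4.42. SLC26A4 fell from 90.3 ± 27.6 to 1.86 ± 0.484 FPKM (log2 -5.23 ± 0.25). CES1, the glucose-6-phosphatase family gene G6PC2, BEST2 and PPP1R1B had log2 fold changes of -3.68, -3.12, -2.97 and -2.66. Across all genes the surgery effects at the 2 ages, which share no library, correlated with r = 0.80 and rho = 0.77, where genes are not independent replicates. Of the genes that rose, 1540 did so at both ages against 343.4 for independent lists, and of those that fell 2146 against 809.8.

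Of 8 coagulation genes 4 rose and 2 fell in juveniles, or 5 and 2 adjusted over the list alone (camera adjusted p = 0.0284, adjusted p = 0.133 with an estimated correlation). VWF rose 3.35-fold from 48.5 ± 6.26 to 164 ± 24.2 FPKM, FGL1 2.59-fold, TGM2 1.69-fold and F3 1.55-fold, while GGCX and VKORC1, enzymes of the vitamin K cycle, were each 1.21-fold lower. The VKORC1 call was lost with 6.5-week operated eyes alone (adjusted p = 0.263) and without the 3 5-week samples whose label numbers come after those of the 6-month samples, the late-numbered samples (adjusted p = 0.0907). F5 did not pass (log2 0.92 ± 0.38, adjusted p = 0.0578), but passed without 5-week unoperated replicate 3 or 4, 5-week operated replicate 3 or 6.5-week operated replicate 3 (adjusted p down to 0.019), and with 6.5-week operated eyes alone (log2 1.64, adjusted p = 0.00906). Of 12 fibrinolysis and anticoagulant genes 6 rose and 1 fell, the same counts adjusted over the list alone (camera adjusted p = 0.0024, adjusted p = 0.0481 with an estimated correlation). PLAUR rose 4.39-fold, PROCR 3.15-fold and urokinase (PLAU) 1.84-fold, and PROS1 fell by 0.39 on the log2 scale.

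Of 18 complement genes 16 rose in juveniles, and 16 adjusted over the list alone (camera adjusted p = 2.74e-13, adjusted p = 0.00825 with an estimated correlation). CLU rose 14.1-fold, C1S 5.42-fold, C1R 4.72-fold and SERPING1 3.52-fold. C2, C4A and C3 rose 2.85-fold, 2.57-fold and 2.1-fold, with C3 at 74.2 ± 59.3 FPKM in operated eyes, and the C3 call was lost with 6.5-week operated eyes alone (adjusted p = 0.166). Of 27 acute phase genes 20 rose and 1 fell, the same counts adjusted over the list alone (camera adjusted p = 2.65e-16, adjusted p = 0.00825 with an estimated correlation). Of 27 cytokines 17 rose, and 17 adjusted over the list alone (camera adjusted p = 5.01e-10, adjusted p = 0.0342 with an estimated correlation), among them CCL7 21.3-fold, the chemokine GRO-B 5.09-fold and the interleukin 1 antagonist IL1RN 4.83-fold. Of 15 eicosanoid genes 7 rose and 2 fell, or 8 and 2 adjusted over the list alone (camera adjusted p = 0.00491, adjusted p = 0.0481 with an estimated correlation), with PTGS2 up 4.63-fold.

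All 22 measured macrophage genes rose in juveniles, 22 also adjusted over the list alone (camera adjusted p = 2.65e-16, adjusted p = 0.0481 with an estimated correlation). TYROBP rose 4.94-fold, CD163 9.2-fold and CD209 12.8-fold. Of 10 neutrophil genes 9 rose and 1 fell, the same counts adjusted over the list alone (camera adjusted p = 6.08e-07, adjusted p = 0.0607 with an estimated correlation), with S100A8 up 9.83-fold and MMP9 7.02-fold. Of 15 antigen presentation genes 13 rose, and 13 adjusted over the list alone, CD74 4.54-fold and RLA-DR-ALPHA 4.73-fold (camera adjusted p = 1.88e-06, adjusted p = 0.166 with an estimated correlation). The count was 8 without 5-week operated replicate 3, whose mean level of this list was 6.19 against 4.49 to 4.81 in the other operated juveniles, and 6 with 6.5-week operated eyes alone. The plasma cell genes JCHAIN, MZB1 and XBP1 rose 10.8-fold, 6.79-fold and 1.6-fold. The T cell genes CD3D, CD3E and LCK rose 3.58-fold, 3.49-fold and 3.23-fold, and each call was lost without 5-week operated replicate 3 (adjusted p = 0.0583, 0.0639 and 0.0859) and with 6.5-week operated eyes alone (adjusted p = 0.231, 0.264 and 0.228). Without that replicate CD3E went from log2 1.80 to 1.14 and LCK from 1.69 to 1.06.

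Of 38 cell cycle genes 25 rose in juveniles, or 28 adjusted over the list alone (camera adjusted p = 5.76e-10, adjusted p = 0.163 with an estimated correlation), CCNB2 2.65-fold, AURKA 3.74-fold and CCNB1 2.77-fold. Of 22 immediate early and stress genes 18 rose, or 19 adjusted over the list alone (camera adjusted p = 6.78e-11, adjusted p = 0.0709 with an estimated correlation), and of 19 endothelial genes 11 rose and 1 fell, or 12 and 1 adjusted over the list alone (camera adjusted p = 4.47e-06, adjusted p = 0.126 with an estimated correlation).

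Resident tissue genes fell in juveniles as well. Of 24 ciliary transport genes 16 fell and 2 rose, the same counts adjusted over the list alone (camera adjusted p = 4.47e-06, adjusted p = 0.0748 with an estimated correlation). Of 13 junction genes 9 fell and 2 rose, the same counts adjusted over the list alone (camera adjusted p = 0.00212, adjusted p = 0.0718 with an estimated correlation), with CLDN19 3.81-fold, F11R 1.81-fold and OCLN 1.69-fold lower. Of 14 pigment genes 11 fell and 1 rose, or 12 and 1 adjusted over the list alone (camera adjusted p = 3.08e-05, adjusted p = 0.0709 with an estimated correlation), PMEL 4.35-fold and OCA2 2.27-fold lower. In smooth muscle, 9 of 18 genes fell and 2 rose, or 11 and 2 adjusted over the list alone (camera adjusted p = 0.0675), with MYH11 1.82-fold lower and DES 1.81-fold higher. Of 21 basement membrane genes 12 fell and 4 rose, the same counts adjusted over the list alone (camera adjusted p = 0.0284, adjusted p = 0.464 with an estimated correlation), COL9A1 5.98-fold and NID2 1.94-fold lower. Of 10 growth-associated genes 6 fell, and 6 adjusted over the list alone (camera adjusted p = 0.00819, adjusted p = 0.0481 with an estimated correlation), PEG3 2.67-fold and MEST 1.87-fold. Of 40 extracellular matrix genes 14 rose and 9 fell, the same counts adjusted over the list alone (camera adjusted p = 0.0551).

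Surgery changed 4835 genes in juveniles, 2141 higher and 2694 lower, and libraries scaled to an equal sum gave 1545 higher and 4670 lower with the median log2 change moved from -0.056 to -0.176. With operated eyes of 5 weeks alone 3216 genes passed, and 2644 passed without the 8 libraries of all groups that hold over 1000 FPKM of the lens crystallin CRYAA. Random removal of 8 libraries left a median of 2784 genes, with 2644 or fewer in 15 of 50 draws. Without the libraries rich in CRYAA 7 pigment and 7 basement membrane genes fell in juveniles, and 6 antigen presentation and 0 T and NK cell genes rose, the last by limma with 0 at an unadjusted p under 0.05.

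The surgery effect differed with age for 141 genes, 95 with the more positive change at 6 months and 46 with the more positive change in juveniles. CCNB2 rose from 0.547 ± 0.127 to 15.1 ± 4.78 FPKM at 6 months and from 4.0 ± 1.39 to 11.2 ± 2.45 FPKM in juveniles, an age difference of log2 2.46 ± 0.26 (SE; limma adjusted p = 2.01e-05). CDCA3, the proliferation marker MKI67, KIAA0101, CDC20, UBE2C, CCNB1, RRM2 and CDK1 had age differences of 2.92, 2.86, 2.44, 2.41, 2.40, 2.31, 2.31 and 1.93. The MKI67 value was 1.64 (adjusted p = 0.321) with 5-week operated eyes alone, and a pseudocount of 0.1 gave 4.45, 4.91 and 3.81 for CDCA3, MKI67 and CDC20. Of 38 cell cycle genes 24 passed, or 35 adjusted over the list alone (camera adjusted p = 2e-58, adjusted p = 0.00411 with an estimated correlation), with a median change of 2.28 at 6 months and 0.82 in juveniles. Without the libraries rich in CRYAA, where fewer samples are left, 1 of the 38 passed, 30 had an unadjusted p under 0.05, and the median age difference was 1.27 against 1.42 with all libraries.

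Single matrix and growth genes also differed with age in their surgery effect. LOX, which crosslinks collagen, rose from 9.88 ± 1.54 to 27.8 ± 6.74 FPKM at 6 months and stood at 15.5 ± 1.52 and 17 ± 1.76 FPKM in juveniles (age difference 1.29 ± 0.17, limma adjusted p = 0.000155). COL1A1 rose at 6 months (log2 0.49 ± 0.11) and fell in juveniles (-0.44 ± 0.11), an age difference of 0.94 ± 0.15. Those of SPARC, MEST and the matrix protein gene POSTN were 0.63, 0.96 and -1.58. SPARC lost its call without the late-numbered samples and with 5-week or 6.5-week operated eyes alone (adjusted p = 0.082, 0.0515 and 0.0587), MEST with 5-week eyes alone (0.06), and POSTN with 6.5-week eyes alone or covariates (0.0851 and 0.0507). COL4A1 (1.39), COL4A2 (0.91) and IGF2BP2 (0.64) passed, but the calls were lost in 7, 17 and 10 of 26 fits that each left out 1 library (adjusted p up to 0.0607, 0.0841 and 0.0704). COL4A1 and COL4A2 stood at 0.85 and 0.53 without the libraries rich in CRYAA (adjusted p = 0.256 and 0.38). The single libraries whose removal ended the COL4A1 call, each left out alone, were 5-week unoperated replicate 2, 5-week operated replicate 2, 6.5-week operated replicate 2, 6-month unoperated replicate 4 and 6-month operated replicates 1, 2 and 4. Of 40 matrix genes 3 were more positive at 6 months and 1 in juveniles, or 4 and 1 adjusted over the list alone (camera adjusted p = 0.00117, adjusted p = 0.427 with an estimated correlation). Of 21 basement membrane genes 2 passed, or 5 adjusted over the list alone (camera adjusted p = 0.00056, adjusted p = 0.427 with an estimated correlation). Of 10 growth-associated genes 2 passed, or 4 adjusted over the list alone (camera adjusted p = 0.566).

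Of 8 coagulation genes FGL2 differed with age, or 2 genes adjusted over the list alone. It fell at 6 months and stood at 15.0 ± 2.87 and 17.5 ± 9.35 FPKM in unoperated and operated juvenile eyes (age difference -1.49 ± 0.28, limma adjusted p = 0.00697; list camera adjusted p = 0.778). Of 12 fibrinolysis genes SERPINE2 passed with 0.82, or 2 genes adjusted over the list alone (camera adjusted p = 0.0363, adjusted p = 0.358 with an estimated correlation), and its call was lost in 23 of 26 fits that each left out 1 library (adjusted p up to 0.0918) and in 7 other settings (adjusted p up to 0.416). No complement gene passed in limma, while 7 of 18 had an unadjusted p under 0.05 and 4 passed adjusted over the list alone, each more positive in juveniles (camera adjusted p = 0.00653, adjusted p = 0.427 with an estimated correlation). Of 27 acute phase genes SOCS3 passed (-0.92, adjusted p = 0.0722 with 6.5-week operated eyes alone), or 2 genes adjusted over the list alone (camera adjusted p = 0.711). The neural genes NRGN and SYNPR, CYP26C1 and the growth factor gene FIGF had age differences of -2.30, -2.20, -1.89 and -1.38, and with 5-week operated eyes alone SYNPR and FIGF did not pass (adjusted p = 0.124 and 0.183). Among unoperated eyes NRGN, SYNPR, CYP26C1 and FGL2 were higher at 6 months than at 5 weeks. Their age differences may therefore reflect the starting level, which was not tested apart from a different response to surgery. The macrophage, antigen presentation, red cell, smooth muscle, junction, Schwann cell and immediate early lists also passed camera (adjusted p = 0.0395, 0.0363, 0.02, 0.00739, 0.00739, 0.0395 and 0.0366), and none of them with an estimated correlation (adjusted p = 0.77, 0.77, 0.432, 0.486, 0.358, 0.486 and 0.77).

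Median-ratio scaling gave 112 and 28 genes in place of 95 and 46. Without the 8 libraries rich in CRYAA 3 genes passed (CDCA3, CCNB2 and NRGN), while random removal of 8 libraries left a median of 32 genes over 50 draws and 3 or fewer in 2 of them.

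**Figure D3:**
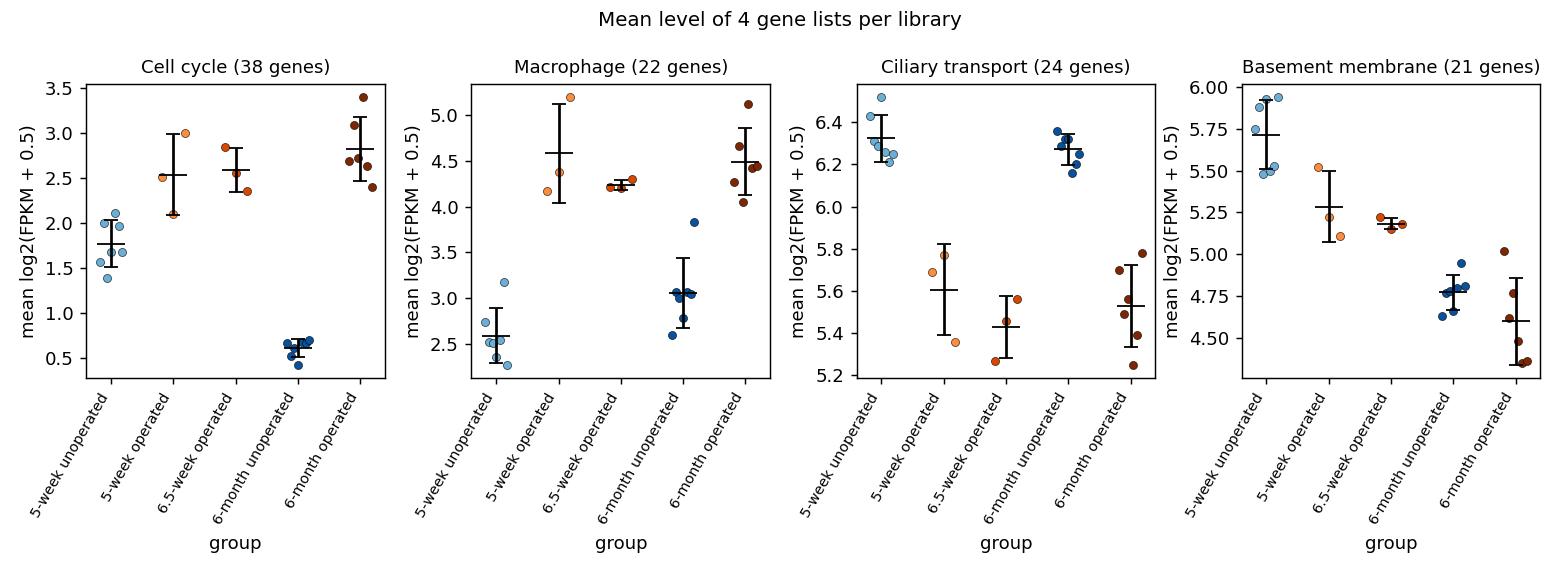
Mean log2(FPKM + 0.5) of the measured members of 4 gene lists in each library, by group, with black bars for the group mean and its SD. Cell cycle levels lie between 0.42 and 0.7 in the 7 unoperated 6-month libraries, below all others, and ciliary transport levels are lower in the operated groups.

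Among unoperated eyes, 6-month eyes (n = 7) had lower cell cycle and matrix levels than 5-week eyes (n = 7). Of 38 cell cycle genes 32 fell with age, or 34 adjusted over the list alone (camera adjusted p = 3.64e-28, adjusted p = 0.0313 with an estimated correlation), CCNB2 4.16-fold, CCNB1 3.93-fold, CDK1 3.37-fold and TOP2A 3.26-fold. Of 21 basement membrane genes 19 fell, and 19 adjusted over the list alone (camera adjusted p = 4.32e-21, adjusted p = 0.00593 with an estimated correlation), with COL9A3 3.12-fold, COL4A2 2.65-fold, COL4A5 2.5-fold and NID2 2.07-fold lower. Of 40 extracellular matrix genes 20 fell and 4 rose, or 21 and 4 adjusted over the list alone (camera adjusted p = 1.42e-10, adjusted p = 0.0313 with an estimated correlation). The 4 were 2 without 6-month replicate 5 or 7. COL1A1 fell from 1930 ± 138 to 579 ± 95.5 FPKM (SD), FBN2 3.44-fold, COL3A1 2.17-fold and COL5A1 2.16-fold. Of 10 growth-associated genes 4 fell, and 4 adjusted over the list alone (camera adjusted p = 0.000236, adjusted p = 0.00842 with an estimated correlation), MEST, IGF2BP2, PEG3 and NREP by 2.66-fold, 2.23-fold, 2.23-fold and 2.22-fold.

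The neural genes NRGN (log2 3.56 ± 0.30) and SYNPR (3.39 ± 0.30), CYP26C1 (2.38), the zinc transporter SLC30A3 (2.03) and F5 (2.0) rose with age. F5 went from 2.61 ± 1.19 to 11.3 ± 3.25 FPKM (limma adjusted p = 0.000413) and FGL2 from 15.0 ± 2.87 to 56.8 ± 6.0 FPKM, so that 2 of 8 coagulation genes rose, or 3 rose and 1 fell adjusted over the list alone (camera adjusted p = 0.333). Of 12 fibrinolysis genes 1 rose and 2 fell, or 2 and 2 adjusted over the list alone (camera adjusted p = 0.602). SERPINE2 and THBD were 1.45-fold and 1.34-fold lower and PROS1 1.19-fold higher, the last a call lost with upper-quartile and equal-sum scaling (adjusted p = 0.0611 and 0.131) and without the late-numbered samples (0.0572), while the THBD call was lost with covariates (0.0695). ALOX15, a lipoxygenase, fell from 3.88 ± 2.3 to 0.00286 ± 0.00756 FPKM, and CDCA3, the protease gene ADAMTS17, the lipid receptor gene S1PR3 and CDC20 had log2 changes of -2.31, -2.12, -2.05 and -2.05, that of S1PR3 -1.17 with covariates.

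Some immune genes were higher in unoperated 6-month eyes. Of 18 complement genes 8 rose, or 9 rose and 1 fell adjusted over the list alone (camera adjusted p = 0.000379, adjusted p = 0.25 with an estimated correlation), C7 2.69-fold, MASP1 2.45-fold and SERPING1 1.57-fold. Of 22 macrophage genes 6 rose, or 8 adjusted over the list alone (camera adjusted p = 0.00425, adjusted p = 0.641 with an estimated correlation). Of 15 antigen presentation genes 5 rose, or 8 adjusted over the list alone, RLA-DR-ALPHA 3.17-fold and CD74 2.66-fold (camera adjusted p = 0.0024, adjusted p = 0.641 with an estimated correlation). JCHAIN rose 11.1-fold to 252 ± 200 FPKM and CD3D 3.6-fold. MZB1 rose 2.87-fold and CD3E 3.36-fold, and these calls were lost in 9 and 5 of 14 fits that each left out 1 library (adjusted p up to 0.0746 and 0.063), for CD3E without 5-week replicate 2 or 4 or 6-month replicate 2, 5 or 7. Of 27 cytokines 5 rose and 1 fell, or 6 and 1 adjusted over the list alone (camera adjusted p = 0.18), and of 27 acute phase genes 6 rose, or 7 adjusted over the list alone (camera adjusted p = 0.119). None of 10 neutrophil and 25 interferon genes passed in limma, with 3 and 0 at an unadjusted p under 0.05. With lens and retina transcript levels as covariates CD3D, CD3E and MZB1 did not pass (adjusted p = 0.239, 0.296 and 0.302), and 1 macrophage, 2 antigen presentation, 0 cytokine and 2 acute phase genes rose. Without the libraries rich in CRYAA, 3 complement, 2 macrophage, 1 cytokine, 1 acute phase and 0 antigen presentation genes rose, the last by limma with 3 at an unadjusted p under 0.05. The antigen presentation count was 3 without 5-week replicate 2, 3, 4 or 7 or 6-month replicate 2, 3, 5 or 7, and 10 without 5-week replicate 6. Cytokines numbered 3 without 6-month replicate 6 or 7, and acute phase genes 3 without 6-month replicate 7. Counts were higher without the late-numbered samples, at 12 complement, 9 macrophage, 9 antigen presentation, 9 cytokine and 9 acute phase genes.

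Some smooth muscle and Schwann cell genes rose with age and some red cell genes fell. Of 18 smooth muscle genes 8 rose, or 10 adjusted over the list alone, DES 1.71-fold and LMOD1 1.54-fold (camera adjusted p = 0.00161, adjusted p = 0.437 with an estimated correlation). Of 11 Schwann cell genes 6 rose, or 7 adjusted over the list alone, S100B 1.89-fold and CDH19 1.8-fold (camera adjusted p = 0.00649, adjusted p = 0.32 with an estimated correlation). Of 6 red cell genes HBB2, CA1, ALAS2 and HBZ were 2.81-fold, 2.72-fold, 2.43-fold and 2.32-fold lower and SPTB 1.43-fold higher, the same 4 and 1 adjusted over the list alone (camera adjusted p = 0.0292, adjusted p = 0.493 with an estimated correlation). The SPTB call was lost without 5-week replicate 2, 6 or 7 or 6-month replicate 1, 4 or 5 (adjusted p up to 0.0785), and with upper-quartile scaling (adjusted p = 0.0522). HBB2 did not pass without the late-numbered samples (adjusted p = 0.0552) or with covariates (0.054). Of 14 pigment genes 5 fell, or 5 fell and 1 rose adjusted over the list alone, PMEL 2.17-fold and TYR 1.45-fold (camera adjusted p = 0.0671), and 3 fell without 6-month replicate 4. With covariates 3 smooth muscle and 2 Schwann cell genes rose and 2 pigment genes fell. Without the libraries rich in CRYAA 3 smooth muscle and 2 Schwann cell genes rose, and 1 red cell and 1 pigment gene fell. None of 5 striated muscle genes passed in limma, and 1 had an unadjusted p under 0.05.

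Age changed 2696 genes among unoperated eyes, 1471 higher and 1225 lower at 6 months. By label number the 6-month samples come after all juvenile samples other than the late-numbered ones. Age and sample order are therefore largely not separated, among unoperated and among operated eyes. The counts were 1201 and 1396 with median-ratio, 1018 and 1597 with upper-quartile and 875 and 1652 with equal-sum scaling. CRYAA exceeded 1000 FPKM in 4 of 7 unoperated 5-week and 1 of 7 unoperated 6-month libraries. Without the libraries rich in CRYAA 599 genes passed, among them 18 of the cell cycle and 11 of the basement membrane genes as lower, against a median of 941.5 genes over 50 random removals of 8 libraries, with 599 or fewer in 3 of them, and 1341 passed with lens and retina transcript levels as covariates.

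Among operated eyes, 6-month (n = 6) and juvenile eyes (n = 6) differed in matrix and growth genes. FBN2 fell with age from 5.71 ± 1.26 to 1.63 ± 0.197 FPKM (SD; limma adjusted p = 1.19e-08), and POSTN, the proteoglycan gene VCAN, PEG3, ADAMTS16 and ATXN7L1 had log2 changes of -1.96, -1.74, -1.59, -1.54 and -1.45. Of 21 basement membrane genes 14 fell, or 17 adjusted over the list alone (camera adjusted p = 2.43e-11, adjusted p = 0.0494 with an estimated correlation), LAMA2 2.16-fold, NID2 1.67-fold and LAMB1 1.58-fold. Of 40 extracellular matrix genes 17 fell and 4 rose, or 19 and 6 adjusted over the list alone (camera adjusted p = 0.000195, adjusted p = 0.455 with an estimated correlation), COL6A3 2.36-fold and COL5A1 1.78-fold lower. Of 10 growth-associated genes 7 fell and 1 rose, the same counts adjusted over the list alone (camera adjusted p = 0.000387, adjusted p = 0.0188 with an estimated correlation), NREP 1.68-fold and IGF2BP2 1.43-fold lower. Against 5-week operated eyes alone 4 of the 10 fell, and IGF2BP2 did not pass against 6.5-week eyes alone (adjusted p = 0.13).

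SCG2, SLC30A3, EGR2, CES1 and DIRAS3 were 5.01-fold, 3.24-fold, 3.05-fold, 2.38-fold and 2.32-fold higher in operated 6-month than in operated juvenile eyes. EGR2 lost its call with a pseudocount of 0.1 (adjusted p = 0.0788) and against 5-week eyes alone (0.0953), and SLC30A3 against 6.5-week eyes alone (0.075). Of 8 coagulation genes VWF was lower (164 ± 24.2 against 111 ± 33.2 FPKM) and FGL1 1.48-fold higher, the same 1 and 1 adjusted over the list alone (camera adjusted p = 0.412). In a fit on the compared groups alone neither VWF (adjusted p = 0.0724) nor FGL1 (adjusted p = 0.153) passed, and FGL1 lost its call in 9 of 12 fits that each left out 1 library (adjusted p up to 0.115). TFPI, which also did not pass in that fit (adjusted p = 0.118), was 1.46-fold higher (log2 0.55, or 0.35 without 6.5-week operated replicate 3) and C7 1.92-fold higher, and C7 lost its call in 10 of 12 fits that each left out 1 library (adjusted p up to 0.109). PTGS1 was 1.52-fold higher, a call lost without 6.5-week operated replicate 1 or 6-month operated replicate 6 (adjusted p up to 0.058) and on the compared groups alone (adjusted p = 0.0547). Against 6.5-week eyes alone the log2 values of PTGS1 and FGL1 were 0.06 (adjusted p = 0.9) and 0.11 (adjusted p = 0.826). ALOX15 was lower (2.01 ± 2.65 against 0.01 ± 0.0167 FPKM, log2 -1.50), while the value against 6.5-week eyes alone was 0.01 (adjusted p = 0.993). No cell cycle gene passed in limma and 5 of 38 had an unadjusted p under 0.05, with a median of 0.23 (camera adjusted p = 0.00313, adjusted p = 0.841 with an estimated correlation). Of 22 immediate early genes 2 rose, or 4 adjusted over the list alone (camera adjusted p = 0.00102, adjusted p = 0.801 with an estimated correlation).

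In total 2027 genes changed with age among operated eyes, 761 higher and 1266 lower at 6 months, against 1150 and 1070 with median-ratio and 329 and 1996 with equal-sum scaling. A fit on the compared groups only gave 818 genes and the 6.5-week operated eyes alone 1182. Of the genes higher at 6 months, 372 were so among both unoperated and operated eyes against 86.5 for independent lists, and of those lower 623 against 119.8. Sample order ran largely with age in both, so this overlap cannot tell age from order.

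Operated eyes of 6.5 and 5 weeks (n = 3 each) differed in 2 genes. AMOTL2, a junction gene of the angiomotin family, was 1.61-fold higher at 6.5 weeks (20.6 ± 0.682 against 33.6 ± 1.09 FPKM, SD; limma adjusted p = 0.000323). ALOX15 stood at 4.01 ± 2.34 FPKM at 5 weeks and 0.00667 ± 0.0115 FPKM at 6.5 weeks (adjusted p = 0.000673). At an unadjusted p under 0.05 there were 1339 genes. The count was 78 without 6.5-week operated replicate 2, 5 without 6.5-week replicate 3, and 6 and 4 without 5-week operated replicates 2 and 3. In a fit on the 6 libraries alone neither AMOTL2 (adjusted p = 0.313) nor ALOX15 (adjusted p = 0.306) passed. Of 30 gene lists 10 passed camera, among them smooth muscle (median log2 0.32, adjusted p = 0.00158) and neutrophil genes (-0.73, adjusted p = 0.000257), while the lowest adjusted p with an estimated correlation was 0.383.

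Transcripts of the lens varied widely within groups. CRYAA ranged from 0.11 to 16800 FPKM among unoperated 5-week, from 0 to 1320 among unoperated 6-month and from 0.05 to 1680 among operated 6-month libraries. Of 7 lens genes HSF4 fell at 6 months (1.52-fold, a call lost without operated replicate 4, adjusted p = 0.0691, and with covariates, adjusted p = 0.0734) and CRYGN in juveniles (2.74-fold, log2 -1.46, or -0.91 without the libraries rich in CRYAA), or 0 and 1 adjusted over the list alone (camera adjusted p = 0.613 and 0.563).

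**Figure D4:**
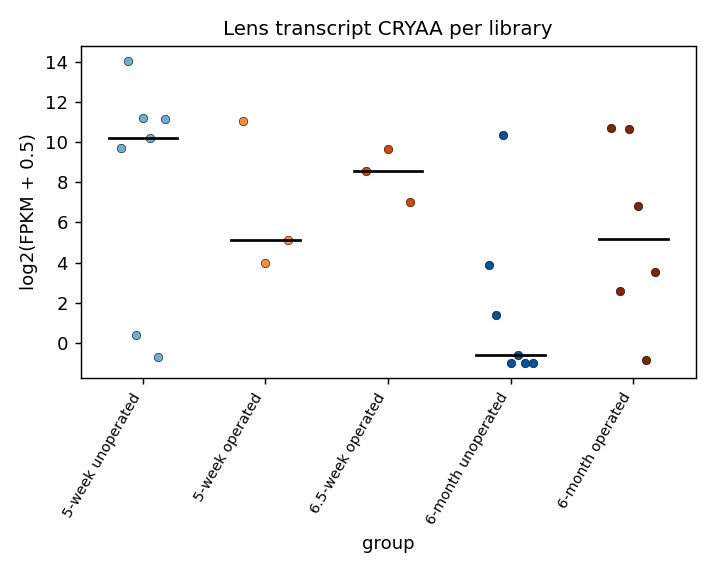
Log2(FPKM + 0.5) of CRYAA (lens) in each library, by group, with a line at the group median. CRYAA reaches 16800 FPKM in an unoperated 5-week library, and 4 of the 7 libraries of that group exceed 1000 FPKM.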

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

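The tests of explanations in this part were chosen after the results were seen.

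The mean log2 level of gene lists in single libraries stood apart from the other libraries of the group in 8 of 96 checks, where chance gives about 1 in 20, or 4.8. The checks also covered the FPKM sum and the number of transcripts at 0, in which no library stood apart from its group. They compare libraries within a group and cannot show a shift between groups. Both operated juvenile groups, of 3 libraries each, were too small to be checked. Unoperated 5-week replicate 6 was the library in 6 of them. Its levels were 6.16 for interferon genes (others 2.75 to 4.19), 4.63 for antigen presentation (3.12 to 3.59), 5.45 for complement (4.8 to 4.94), 2.57 for cytokines (1.27 to 1.55), 3.49 for acute phase genes (2.98 to 3.17) and 1.84 for T and NK cell genes (-0.48 to 0.52). Unoperated 6-month replicate 7 stood at 3.83 for macrophage genes (2.6 to 3.07), and unoperated 6-month replicate 3 at 6.86 for lens genes (2.02 to 3.76). Outside these checks, 5-week operated replicate 3 stood at 4.43 for T and NK cell genes, against 0.64 to 1.09 in the other operated juveniles. Like unoperated 5-week replicate 6 it is a late-numbered sample, and the labels do not say whether these share a batch.

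The change with surgery differed between the ages for 141 genes by limma. The log2 age differences were 2.92 for CDCA3, 2.86 for MKI67, 2.46 for CCNB2, 2.44 for KIAA0101, 2.41 for CDC20, 2.4 for UBE2C, 2.31 for CCNB1 and RRM2 and 1.93 for CDK1. For matrix and growth genes they were 1.39 for COL4A1, 1.29 for LOX, 0.96 for MEST, 0.94 for COL1A1, 0.91 for COL4A2, 0.64 for IGF2BP2, 0.63 for SPARC and -1.58 for POSTN. For SERPINE2 of the fibrinolysis list the value was 0.82, a call lost in 23 of 26 fits that each left out 1 library. The remaining values were -2.3 for NRGN, -2.2 for SYNPR, -1.89 for CYP26C1, -1.49 for FGL2, -1.38 for FIGF and -0.92 for SOCS3.

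The median log2 change of the 38 cell cycle genes was 2.28 at 6 months, where 37 rose, and 0.82 in juveniles, where 25 rose. The juvenile list did not pass camera with an estimated correlation. Values near the floor are not the whole cause of the age difference, a median of 1.42 over 38 members, since the 15 members that averaged at least 1 FPKM in unoperated 6-month eyes had a median of 0.95 (median SE 0.24), all 15 above 0. Over the list a pseudocount of 1, which weighs low values less, gave 1.10 and a pseudocount of 0.1 gave 1.82, so low values affect the size of the median. Libraries rich in lens transcripts do not account for the median, which was 1.27 without them, within the range of 1.063 to 1.819 for random removals, although 1 member was then called in place of 24. The lower level of unoperated 6-month eyes made up 83.7% of the median age difference, and operated eyes of both ages differed by a median of 0.23. By construction the age difference is the age change among operated eyes minus that among unoperated eyes, so this share describes the group levels and is no separate test. The age difference may reflect the starting level, and the biology of age itself was not tested.

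Lens transcripts may come from lens tissue carried into some samples, since CRYAA, CRYBB2 and CRYGS were highest in the same library in 4 of 5 groups. Unoperated eyes keep their lens, so its removal could not cause their spread, where log2(FPKM + 0.5) of CRYAA ranged over 14.75 units at 5 weeks and 11.36 at 6 months. The part of lens removal in the spread among operated eyes (7.03, 2.64 and 11.57 units at 5 weeks, 6.5 weeks and 6 months) stays open. Median CRYAA was 0.17 FPKM in unoperated and 61.8 FPKM in operated 6-month eyes. It was 1200 FPKM in unoperated 5-week eyes and 34 and 371 FPKM in operated 5-week and 6.5-week eyes. No biological explanation was tested.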

How the results depend on the processing

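Of the alternatives, single transcripts, a mean of at least 5 FPKM, equal-sum scaling, lens and retina covariates and leaving out the libraries with CRYAA above 1000 FPKM were chosen after seeing the data. The rule allowed 1017 gene values over the 6 comparisons; the 256 in the text were picked among these after their values were known, apart from the surgery effects of LOX and COL1A1. Several with unstable calls were at first left out and then restored, so counts over the named values may still look more stable than those over all allowed. Recomputed 7166 times, the named values kept direction and call in 6790, lost the call in 354, gained it in 12 and turned in 10. Over all allowed values the numbers were 26364 of 28153, 1153, 291 and 345, where 2 of the turned ones belonged to called genes. The values that turned were C3 at 6 months (main log2 -0.01), at 0.09 with median-ratio and 0.039 with upper-quartile scaling, 0.119 with covariates, 0.003 without the libraries rich in CRYAA, and from -0.15 to 0.169 with each library left out, where it turned without unoperated replicate 6 (0.018) or 7 (0.169) or operated replicate 3 (0.015), 5 (0.05) or 6 (0.003), and ALOX15 among operated eyes, at 0.009 with 6.5-week eyes alone. Requiring a 2-fold change, which by construction removes genes, left 912, 869, 286, 149, 79 and 1 of 5969, 4835, 2696, 2027, 141 and 2 genes (surgery at 6 months and in juveniles, age in unoperated and operated eyes, the age difference in the surgery effect, and 6.5 against 5 weeks). Without the libraries rich in CRYAA, which also means fewer samples, 2644 genes passed in juveniles, 599 and 1305 for age in unoperated and operated eyes and 3 for the age difference. Random removals of 8 libraries left medians of 2784, 941.5, 1158.5 and 32 genes for these 4 counts. Among the 256 named values, not all of which were called with all libraries, 56 calls were lost without the libraries rich in CRYAA. A pseudocount of 0.1 moved 16 called named values by over 1.5 times, each of a gene that averaged under 1 FPKM in at least 1 group. With covariates 1341 passed for age in unoperated eyes. With 5-week operated eyes alone 3216 passed in juveniles and 84 for the age difference; with 6.5-week eyes alone 1182 for age in operated eyes; on the compared groups only, 818. With a mean of at least 5 FPKM, where fewer genes are tested, 68 passed for the age difference and 1 for 6.5 against 5 weeks, and leaving out the late-numbered samples gave 4 in the last. At that mean 2 neutrophil and 7 cytokine genes rose at 6 months in place of 8 and 15, and 3 and 9 in juveniles in place of 9 and 17. The cause was not tested for the others. Leaving out each library in turn gave 5101 to 5898, 4303 to 5004, 2219 to 2698, 1562 to 2209, 107 to 220 and 2 to 78 genes, with 220 without 6.5-week operated replicate 3 and 78 without 6.5-week operated replicate 2. Of 30 gene lists 17, 19, 10, 5, 12 and 10 passed camera, 4, 7, 4, 2, 1 and 0 with an estimated correlation (3 lists of the last at an unadjusted p under 0.05), and 20, 22, 11, 3, 1 and 0 the fry test (lowest adjusted p of the last 0.137). Both filters on low values removed no gene and so test nothing. Yet they are counted in both totals of recomputed values, with all 256 named values unchanged under each. Those totals also count the 2-fold rule, which removes calls by construction. Alternatives that need counts, and all those for the cornea and for the difference between tissues, were not run. No paired analysis was possible because no number in the labels occurs in more than 1 iris library. The unknown read depth limits what can be said of low genes.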

Other observations

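The tests of explanations in this part, including the divisions of the samples, were written down after the results were seen.

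Further gene groups moved with surgery. HIF1A, the hypoxia-inducible transcription factor, rose 3.27-fold at 6 months and 2.6-fold in juveniles, and NDRG1 2.3-fold and 3.01-fold. Of 24 hypoxia and glycolysis genes 10 rose and 2 fell at 6 months, PFKP 1.88-fold lower, and 9 rose and 1 fell in juveniles, the same counts adjusted over the list alone (camera adjusted p = 0.00221 and 0.00228, adjusted p = 0.215 and 0.175 with an estimated correlation). PDPN and LYVE1, markers of lymphatic endothelium that other cells also express, rose 3.26-fold and 2.22-fold at 6 months and 2.8-fold and 1.51-fold in juveniles, while RELN was 2.22-fold and 2.1-fold lower. The juvenile LYVE1 call was lost without 5-week operated replicate 2 or 6.5-week operated replicate 3 (adjusted p up to 0.0709) and in 5 other settings (adjusted p up to 0.0916), and that of RELN with 5-week operated eyes alone (adjusted p = 0.0954). ITGA2B, the measured platelet gene, was 1.64-fold lower at 6 months and 1.51-fold lower in juveniles, and the red cell gene SPTB 1.49-fold and 1.68-fold lower.

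At 6 months 7 of 15 antigen presentation genes rose, and 7 adjusted over the list alone, CD1D 2.93-fold and CCR7 3.53-fold (camera adjusted p = 0.00131, adjusted p = 0.391 with an estimated correlation). Of 25 interferon genes DDX58 and IFI35 rose 2.72-fold and 2.02-fold at 6 months and, with IRF1 at 1.91-fold, 2.49-fold and 2.03-fold in juveniles, but 0 passed adjusted over the list alone by limma, with 2 and 3 at an unadjusted p under 0.05 (camera adjusted p = 0.021 and 0.0332, adjusted p = 0.789 and 0.702 with an estimated correlation). Leaving out 1 library ended the IFI35 call in 7 of 13 fits at 6 months and 9 of 13 in juveniles, and the juvenile DDX58 and IRF1 calls in 3 and 10 of 13 (adjusted p up to 0.087, 0.103, 0.0655 and 0.203). These were unoperated replicates 1, 4, 5 and 6 and operated replicates 2, 3 and 4 for IFI35 at 6 months, and 5-week unoperated replicate 3, 5-week operated replicate 3 and 6.5-week operated replicate 2 for DDX58. The juvenile IRF1 value went from log2 0.94 to 0.54 without 5-week operated replicate 3. Without 5-week unoperated replicate 6, whose interferon level was 6.16 against 2.75 to 4.19 in the rest of its group, 9 interferon genes rose in juveniles (DDX58 adjusted p = 0.000584 and IFI35 adjusted p = 0.000885), and with each other library left out 0 to 3 did. The juvenile DDX58 call was also lost with 5-week or 6.5-week operated eyes alone and on the compared groups alone (adjusted p = 0.0534, 0.11 and 0.0584). With equal-sum scaling IFI35 (adjusted p = 0.0537 and 0.055) and IRF1 (adjusted p = 0.0724) did not pass. None of 5 T and NK cell genes passed in limma at 6 months, and 0 had an unadjusted p under 0.05. Among other tissue markers, LUM rose 2.11-fold and 2.66-fold, DCN was 1.6-fold and 1.61-fold lower, the muscle gene CKM 2.59-fold and 1.85-fold lower and the photoreceptor gene ABCA4 2.0-fold and 2.08-fold lower at 6 months and in juveniles. The CKM value at 6 months went from log2 -1.38 to -0.87 without the libraries rich in CRYAA, and the juvenile DCN value from -0.68 to -0.36 with 6.5-week operated eyes alone. EGR2 rose 4.83-fold and 4.0-fold, and at 6 months the Schwann cell gene S100B was 1.61-fold lower. Of 744 gene ontology terms 46 and 40 passed camera for surgery at 6 months and in juveniles, among them translation, with 37 of 115 genes up and 3 down at 6 months and 49 up and 1 down in juveniles. With an estimated correlation 0 terms passed at either age, and 70 and 68 had an unadjusted p under 0.05.

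Most ciliary transport and pigment genes fell with surgery at both ages, while some rose, and neither list passed camera with an estimated correlation. The log2 changes of the members ran from -3.13 to 0.52 at 6 months and from -3.18 to 0.77 in juveniles. A smaller share of resident cells would lower genes expressed only in 1 kind of them by 1 factor. The SD of the log2 changes of the 38 members was 5.19 times their median SE at 6 months (0.78 against 0.15) and 5.78 times in juveniles. The members come from lists of different cells and may be expressed in other cells too, so this spread cannot tell whether a smaller share is the whole cause. Scaling does not account for the fall, since the list medians were -0.5 or lower under 3 other scalings. A changed share, as all or part of the cause, and a regulated fall both stay open, and surgery itself as a biological cause was not tested apart from them.

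Other divisions of the samples into groups of the same sizes were compared with the real ones. For surgery at 6 months 1 of 100 divisions, the real one, gave as many as 5969 genes, and the highest other gave 2951. For surgery in juveniles it was 1 of 100 with 4835 genes and 3172 as the highest other. For age it was 1 of 100 with 2696 genes (69) among unoperated and 1 of 100 with 2027 genes (1255) among operated eyes. For the age difference in the surgery effect the samples were not divided anew. Instead, the deviations of the libraries from a model without that difference were shuffled within each treatment. Of 100 such sets 1, the real one, gave as many as 141 genes, and the highest other gave 117. No other division or shuffled set thus reached the real count in these comparisons, with the narrowest margin for the age difference. The listed transcripts had been chosen by the real groups, which favours the real division. In the other divisions the real differences add to the spread within groups, which lowers their counts. Chance is therefore less likely as a source of these counts but is not excluded. For 6.5 against 5 weeks 2 of 10 divisions gave 2 genes or more and the highest other gave 19, and 10 divisions are too few to reach a share under 0.05.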
